A study of Homo sapiens with 12 samples.

How the data were processed

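RNA was measured by sequencing of poly(A)-selected libraries from 12 samples, per the labels' protocols. Per the submitters' processing notes, the tools named are Trim Galore 0.5.0, RSEM 1.2.22, Bowtie2, DESeq2 1.24 and R 3.6.0, with the genome hg38. The values are expected counts, whole numbers in the authors' deposited table, 1 column per library, not scaled to depth, and were taken as RSEM estimates rounded by the authors. The same deposited table gives the authors' log2 fold change for each of the 6 comparisons. It also gives the authors' adjusted p-value, left empty where the authors gave none. The annotation the authors used is not given in the sources used here. The table holds 23493 genes, of which 98.9% were found by identifier in GENCODE 29, which gave coordinates, and 18199 carried a symbol.

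Libraries were grouped by their labels into 4 groups of 3. The labels give 2 clones of the REC8 line whose columns carry the population names p2 and p3, so these libraries kept their group, were treated as clones and were called A and B. Total counts ran from 2202836 to 18614829 per library. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 12604 genes with at least 99.3% of each library's counts. The 6 comparisons were contrasts of 1 quasi-likelihood fit to all 12 libraries with TMM factors and 8 residual degrees of freedom, and genes were called at an adjusted p below 0.05 after Benjamini-Hochberg correction within each comparison. An F test over the 4 groups came from the same fit. The biological coefficient of variation was 13.6%. CPM values use each library's total over the tested genes times its TMM factor. Log2 CPM values use a prior count of 2, and the SE of a fold comes from its F statistic. Where a group had no count, folds were set against a floor of 3 counts over the group.

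The design, the alternatives listed first, the 30 gene lists and the rule for named genes were written before the data were examined. By that rule the 4 transgenes were named, then genes called with no overlap between the groups and at least 1 CPM in the higher group, by size of fold. These were up to 8 in each direction in 4 comparisons and up to 5 in the REC8 and RAD21L lines against parental cells. Up to 4 called members of each list with the smallest adjusted p were added, and genes without an official symbol were left out. Of the genes this rule picked 2 are not reported here, and no other genes took their place. The 22 lists with at least 5 measured members were tested by camera of limma 3.58.1 with a preset correlation of 0.01, corrected over the lists of a comparison. They were lists of mitotic cohesin and regulators, condensin and SMC5/6, mitosis, DNA replication, homologous recombination, p53 targets, meiosis, interferon-stimulated genes, NF-kB and inflammatory genes, stress response, hypoxia, cholesterol biosynthesis, Wnt targets, intestinal differentiation, epithelial genes, mesenchymal genes, histones, HOX clusters, imprinted genes, immediate early genes, apoptosis regulators and ribosomal proteins. The transgenes were reported by gene.

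Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter of 5 CPM in 3 libraries, a fit of the 6 libraries compared, a log2 fold of at least 1 in size, population or clone as a covariate, leaving out the 4 clones, leaving out each library in turn, and the replicate number as a block. Estimated correlations and fry were used for lists. Thinning of parental p1, limma-voom with quality weights, removal of a loess trend on GC content and length (span 0.4), leaving out both REC8 clones, and leaving out chromosome 2 were added after the data were seen. Correlations of fold changes that share controls were set beside 20 simulated sets of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and figures.

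The pipeline was tested on simulated data with 100 genes changed by a log2 fold of 1 in size and 100 by 2 in each comparison. Between 61% and 74% of the smaller and between 92% and 95% of the larger changes were called, with 7 to 12 false calls among 164 to 178. DESeq2 called 88% of the changed genes with 22 false calls and the fit with the GC and length trend removed 85% with 10. Of 22 lists the 1 that was shifted was called, and a shift of -0.3 of chromosome 2 in 1 library was estimated at -0.27. The simulated genes were independent, and each had the same dispersion in every group. The list test was thus not tried on correlated genes, nor the gene test on groups that differ in spread.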

Results

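RNA-seq libraries from 12 samples of DLD-1, a human colorectal adenocarcinoma cell line, were compared. Per the labels, 3 libraries came from parental cells and 3 from a double line carrying transgenes for STAG3 and SMC1B. Another 3 came from a line that also carried REC8 (REC8 line), and 3 from a line that carried RAD21L in place of REC8 (RAD21L line). By the labels all 3 lines also carried rtTA, the activator that doxycycline turns on, and parental cells carried no transgene, so each comparison with parental cells includes that difference too. STAG3, SMC1B, REC8 and RAD21L (gene RAD21L1) are subunits of the cohesin ring that germ cells make in meiosis. Every culture received 200 ng/ml doxycycline for 72 hours, so no line was compared with and without its transgenes induced, and a line's transgenes could not be separated from its selection and cloning. The parental and double line libraries were populations (p1, p2 and p3). The REC8 and RAD21L lines each had 1 population (p1) and 2 clones. The clones are named c1 and c2 in the RAD21L line and called A and B here in the REC8 line, because the labels name them as clones while their columns carry the population names p2 and p3. They were treated as clones wherever clones were left out or origin was a covariate, and which name is right stayed open. Without the clones the REC8 and RAD21L lines had 1 library each, so the spread in such a fit came from the parental and double line libraries alone. Expected counts summed to 18614829 in parental p1. In the other libraries they ran from 2202836 in REC8 line B to 3531985 in RAD21L line c2. The replicates were separate samples by their labels, and p-values measure the spread between these samples. Levels are CPM, a count scaled to its library's total over the tested genes times the TMM factor, as mean ± SD with n = 3 per group. Changes are log2 folds ± SE from 3 against 3 libraries, and adjusted p-values come from the edgeR quasi-likelihood test over the 12604 genes tested. Coordinates refer to GRCh38 with GENCODE 29 genes.

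The transgenes followed the labels. STAG3 (chromosome 7, 100177563 to 100221488) was at 13.1 ± 0.410 CPM in parental cells, 1454 ± 119 in the double line, 3251 ± 1363 in the REC8 line and 2666 ± 889 in the RAD21L line. SMC1B (chromosome 22, 45344063 to 45413619) was at 0.424 ± 0.424, 567 ± 131, 1427 ± 653 and 2884 ± 639 CPM in the same order. REC8 (chromosome 14, 24171853 to 24180257) reached 7414 ± 2856 CPM in the REC8 line against 5.54 ± 1.40 in parental cells and 4.75 ± 1.05 in the double line. RAD21L1 (chromosome 20, 1226056 to 1296421) had no count outside the RAD21L line, where it stood at 1309.6 ± 64.0 CPM. Against a floor of 3 counts over each group's summed libraries, this was at least 10973-fold higher than in parental cells, 3995-fold higher than in the double line and 3139.9-fold higher than in the REC8 line, a floor that covers counting error only. A gene's count adds the transgene's reads to those of the endogenous gene. The lines differed in the transgenes they shared: in the RAD21L line SMC1B was higher than in the double line (log2 2.34 ± 0.28, adjusted p = 0.000332). STAG3 was also called higher there (log2 0.87 ± 0.25, adjusted p = 0.0333). That call ended when any 1 of the 6 libraries compared but RAD21L line p1 was left out (adjusted p up to 0.124), with the origin of the libraries as a covariate and without the clones. REC8 itself was higher in the RAD21L line than in the double line (log2 2.07 ± 0.42, adjusted p = 0.00673), at 19.8 ± 8.09 CPM. The authors' deposited table gives this fold as 1.10 with an adjusted p of 0.130.

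**Figure D1:**
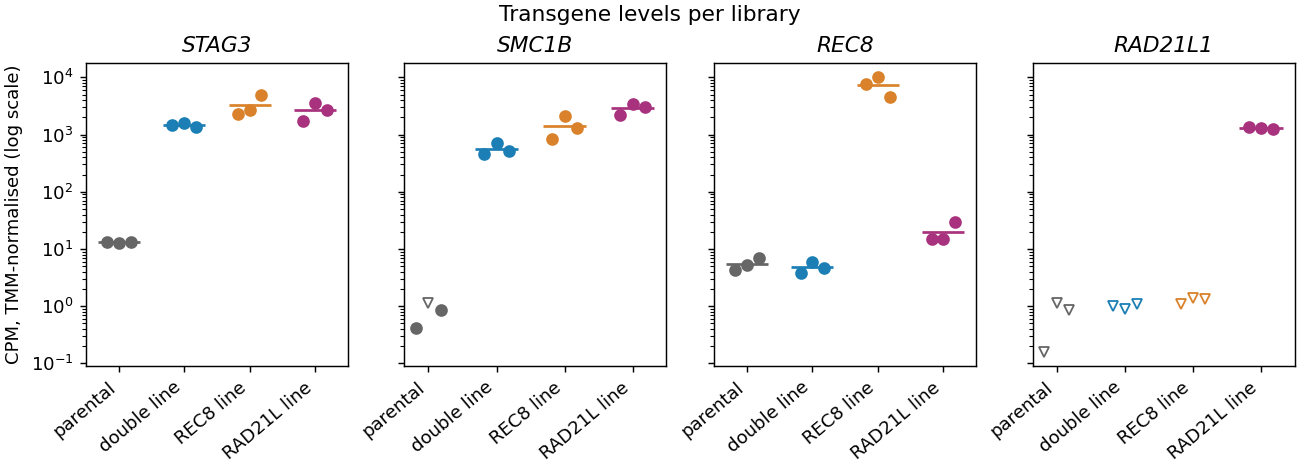
Level of each transgene per library in CPM on a log axis, with open triangles for the floor of 3 counts in libraries without a count. Bars mark the mean of groups in which every library had a count. RAD21L1 lay between 1260.5 and 1382 CPM in the RAD21L line and had no count in the other 9 libraries.

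The double line differed from parental cells in 3 genes by the test over all 12 libraries. Beside STAG3 (log2 6.78 ± 0.33, adjusted p = 3.15e-08) and SMC1B (log2 10.24 ± 0.51, adjusted p = 3.15e-08), ATF3 (chromosome 1, 212565334 to 212620777), a stress-induced transcription factor, rose (log2 1.27 ± 0.19, adjusted p = 0.0403). These 3 genes were the higher genes called by edgeR and 0 were called lower, with 542 genes at an unadjusted p under 0.05, while DESeq2 called 11 higher and 6 lower. ATF3 lost its call without any 1 of the 6 libraries, with adjusted p between 0.120 and 0.576, and with parental p1 thinned to the mean depth of the others (adjusted p = 0.0754). The count varied between fits: 253 genes were called in a fit of these 6 libraries, 250 without the clones of the other lines and 130 with voom weights. The authors' deposited table holds 6 higher and 5 lower genes, and the 3 genes called here were among them.

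Of 22 gene lists camera called 7 in the double line with its preset correlation, and 0 with an estimated correlation, while fry called 0. Genes of the unfolded protein and integrated stress response had a median log2 fold of 0.20 with 25 of 29 measured members above 0 (adjusted p = 8.45e-07 by camera, adjusted p = 0.364 with an estimated correlation). ATF3 was the 1 member called and 28 did not pass, with 2 higher adjusted over the list alone. NF-kB and inflammatory genes had a median of 0.39 over 17 members (adjusted p = 2.11e-05 by camera, adjusted p = 0.364 with an estimated correlation), and 3 were higher adjusted over the list alone. Immediate early and AP-1 genes had a median of 0.31 over 24 members (adjusted p = 2.11e-05 by camera, adjusted p = 0.364 with an estimated correlation). The list also holds ATF3, 23 did not pass, and 5 were higher adjusted over the list alone. Per-library medians against the double line mean were 0.29, -0.20 and -0.05 in double line p1, p2 and p3, and -0.34, -0.27 and -0.20 in the parental libraries, so double line p2 lay level with parental p3. Cytosolic ribosomal protein genes had a median of 0.10, with 41 of 42 members above 0 (adjusted p = 1.13e-05 by camera, adjusted p = 0.680 with an estimated correlation). The libraries overlapped, with medians of -0.07, 0.02 and 0.05 in double line p1, p2 and p3 and -0.01, -0.16 and -0.13 in parental p1, p2 and p3. Wnt targets had a median of -0.32 with 3 of 19 members above 0 (adjusted p = 3.43e-05 by camera, adjusted p = 0.364 with an estimated correlation). Replication-dependent histone genes had a median of -0.67 with 1 of 10 above 0 (adjusted p = 1.13e-05 by camera, adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone, 4 were lower. Hypoxia and glycolysis genes had a median of 0.09 (adjusted p = 0.0428 by camera, adjusted p = 0.369 with an estimated correlation). This call ended without parental p1 (adjusted p = 0.0770), parental p3 (0.121), double line p2 (0.101) or double line p3 (0.0867).

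REC8 was the 1 gene called between the REC8 line and the double line (log2 10.59 ± 0.40, adjusted p = 1.08e-09), so adding REC8 to STAG3 and SMC1B went with no other change that passed for these 3 against 3 libraries. By edgeR 0 genes were called lower and 1584 had an unadjusted p under 0.05. DESeq2 called 25 higher and 50 lower, and the authors' deposited table holds 22 higher and 38 lower. The spread among the REC8 libraries was wide: population p1 lay 0.632 and 0.634 log2 units (root mean square over genes) from clones A and B, against 0.401 to 0.450 among the double line libraries. Without REC8 line p1, 191 genes were called. STAG3 and SMC1B had log2 folds of 1.16 ± 0.25 and 1.33 ± 0.27 and did not pass, with an adjusted p of 0.183 for both.

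Of the gene lists, epithelial genes had a median of -0.26 in the REC8 line against the double line, with 7 of 29 members above 0 (adjusted p = 0.000774 by camera, adjusted p = 0.657 with an estimated correlation). Their per-library medians against the double line mean were -0.09 in p1, -0.45 in A and -0.28 in B. Immediate early and AP-1 genes had a median of -0.30 with 4 of 24 above 0 (adjusted p = 0.00121 by camera, adjusted p = 0.657 with an estimated correlation). Adjusted over the list alone, 4 were lower. The medians were -0.32 in p1, -0.58 in A and 0.10 in B, against 0.29 in double line p1 and -0.20 in p2. HOX cluster genes had a median of -0.15 with 3 of 23 above 0 (adjusted p = 0.00213 by camera, adjusted p = 0.657 with an estimated correlation). The HOX medians were -0.21, -0.35 and 0.04 in p1, A and B. Replication-dependent histone genes had a median of 0.91 with 10 of 10 above 0 (adjusted p = 0.000774 by camera, adjusted p = 0.657 with an estimated correlation) and 4 higher adjusted over the list alone. Their per-library medians were 0.99, -0.36 and 1.51 in p1, A and B, and without B the adjusted p was 0.0549. Ribosomal protein genes had a median of 0.11 (adjusted p = 0.00261 by camera, adjusted p = 0.688 with an estimated correlation), with -0.07, 0.28 and 0.10 in p1, A and B. Without clone A the adjusted p was 0.679, without double line p1 it was 0.0634, and with origin as a covariate 0.329. The list's mean of 0.12 became -0.06 without the clones. Mitotic cohesin genes and their regulators had a median of -0.15 with 5 of 19 above 0 (adjusted p = 0.0401 by camera, adjusted p = 0.657 with an estimated correlation). This call ended without REC8 line p1 (adjusted p = 0.0991), REC8 line B (0.0991) or double line p2 (0.145), with the GC and length trend removed (0.386), with origin as a covariate (0.137) and without the clones (0.164).

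Against the parental cells the REC8 line differed in 179 genes, 67 higher and 112 lower. Among genes named by size of fold, which were not transgenes, had no overlap between the groups and carried an official symbol, the rises included EEF1A2 (chromosome 20, 63488012 to 63499322), a translation elongation factor of muscle and neurons, from 98.4 ± 7.11 to 744 ± 392 CPM (log2 2.92 ± 0.50, adjusted p = 0.0167). Others were DUXAP8, a transcribed pseudogene (log2 2.87 ± 0.38, adjusted p = 0.00381), CACNB4, a calcium channel subunit (log2 2.74 ± 0.43, adjusted p = 0.0102), and NETO2, a kainate receptor subunit (log2 2.65 ± 0.46, adjusted p = 0.0176). PTGS2, the inducible prostaglandin synthase, was called higher (log2 7.96 ± 1.73, adjusted p = 0.0407) through clone B, which held 1477 CPM against 7.59 in p1 and 2.74 in A, and without B the adjusted p was 0.162. The largest falls among genes so named were in CST1, a secreted cystatin (log2 -3.75 ± 0.67, adjusted p = 0.0186), SPDEF, a transcription factor of goblet cells (log2 -3.69 ± 0.63, adjusted p = 0.0169), and the mucin MUC6 (log2 -3.05 ± 0.56, adjusted p = 0.0208). SPDEF had no count in A and B, and its log2 fold ran from -8.00 to -3.17 over the libraries left out. SH3PXD2A (chromosome 10, 103594027 to 103855543), an adaptor of invadopodia, fell from 52.5 ± 4.29 to 6.49 ± 6.96 CPM (log2 -2.92 ± 0.42, adjusted p = 0.00619).

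By list, 3 of 19 Wnt targets fell, namely EPHB3 (-1.25 ± 0.23), RNF43 (-0.53 ± 0.12) and CD44 (-2.57 ± 0.58), and 16 did not pass. Adjusted over the list alone, 9 were lower. Their median was -0.32 (adjusted p = 0.000116 by camera, adjusted p = 0.679 with an estimated correlation). Among intestinal differentiation genes TFF3, a trefoil factor of goblet cells, fell (log2 -2.01 ± 0.36), 12 did not pass, 4 were lower adjusted over the list alone, and the list had a median of -0.48 (adjusted p = 0.0117 by camera, adjusted p = 0.679 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.23 (adjusted p = 0.0422 by camera, adjusted p = 0.679 with an estimated correlation). The glucose transporter SLC2A1 (1.06 ± 0.14) and the enolase ENO2 (1.27 ± 0.24) rose, 25 did not pass, and 6 were higher and 1 lower adjusted over the list alone. Of 17 NF-kB and inflammatory genes IL18 (0.89 ± 0.19), CXCL5 (1.55 ± 0.34) and PTGS2 rose and 14 did not pass. Camera did not call the list (adjusted p = 0.173). The growth factor gene IGF2, on the imprinted list, fell (log2 -1.15 ± 0.16), and of the immediate early list DUSP6 rose (0.86 ± 0.15) and SPRY4 fell (-1.09 ± 0.19), both feedback inhibitors of growth factor signalling. Ribosomal protein genes had a median of 0.21 with 42 of 42 above 0 (adjusted p = 2.86e-08 by camera, adjusted p = 0.717 with an estimated correlation). The mean of 0.22 became 0.04 without the clones (adjusted p = 0.267). Epithelial genes had a median of -0.23 (adjusted p = 0.00970 by camera, adjusted p = 0.717 with an estimated correlation). HOX cluster genes had a median of -0.20 (adjusted p = 0.0151 by camera, adjusted p = 0.679 with an estimated correlation).

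The REC8 line's calls against parental cells varied with the libraries used. DESeq2 called 174 higher and 262 lower, and the authors' deposited table holds 117 higher and 174 lower. Leaving out parental p1, p2 or p3 left 10, 18 or 15 genes, leaving out clone A left 20, leaving out population p1 gave 695, and without both clones whose columns carry other names 12 were called. With the clones of both lines left out 202 were. Of the 25 named genes called, 6 kept their call with each library left out: the 3 transgenes, DUXAP8, SLC2A1 and IGF2. SH3PXD2A lost its call without parental p1 (adjusted p = 0.0510), and the other 18 without any 1 of the parental libraries, with adjusted p up to 0.181 over the libraries left out. With the origin of the libraries as a covariate 8 genes were called, and of the lists those of epithelial (adjusted p = 0.0609), HOX (0.0834), hypoxia (0.0530) and intestinal genes (0.102) were not called without clone A. The HOX list was also not called without REC8 line p1 (0.0796) or parental p1 (0.0552), and the hypoxia list without REC8 line p1 (0.0931), parental p1 (0.0663) or parental p3 (0.0774), or with the GC and length trend removed (0.0566). The epithelial list was not called without the clones (0.190) and the intestinal list with origin as a covariate (0.0522).

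The RAD21L line differed from the double line in 1568 genes, 762 higher and 806 lower. PRR9 (chromosome 1, 153217584 to 153219317), a proline-rich protein gene of the epidermal differentiation region, rose from 0.444 ± 0.208 to 39.7 ± 25.7 CPM (log2 6.42 ± 0.72, adjusted p = 0.000206). CPA4 (chromosome 7, 130293134 to 130324180), a secreted carboxypeptidase, rose from 0.774 ± 0.225 to 64.8 ± 67.0 CPM (log2 6.34 ± 0.92, adjusted p = 0.00112). The largest fall among genes so named was in SH3PXD2A, from 27.9 ± 7.40 to 2.23 ± 0.482 CPM (log2 -3.65 ± 0.53, adjusted p = 0.00112). DDIT4 (chromosome 10, 72273920 to 72276036), an inhibitor of the growth kinase mTORC1, fell from 252 ± 143 to 26.6 ± 9.36 CPM (log2 -3.26 ± 0.35, adjusted p = 0.000123). The hair keratin-associated genes KRTAP3-1 (log2 4.57 ± 0.65) and KRTAP2-3 (log2 4.47 ± 0.66) rose. So did RGS22, a regulator of G protein signalling (log2 4.52 ± 0.72), ANKRD1, a YAP1 target (log2 4.08 ± 0.67), and ATP8A2, a phospholipid flippase (log2 3.76 ± 0.61). KCNJ8, a potassium channel subunit, fell (log2 -3.49 ± 0.60). The same held for the receptor-associated protein gene TSPOAP1 (log2 -3.26 ± 0.61) and the synaptogyrin SYNGR4 (log2 -2.93 ± 0.58). The groups did not overlap in 31.6% of all tested genes, against 10% by chance for 3 libraries against 3.

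**Figure D2:**
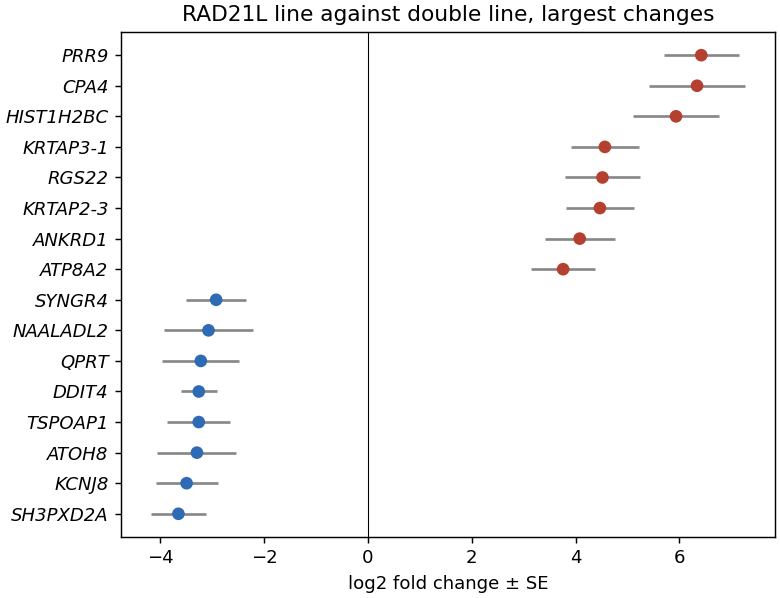
Log2 fold change ± SE of the 8 largest rises and the 8 largest falls that met the naming rule, RAD21L line against double line, 3 libraries per group. The points run from -3.65 for SH3PXD2A to 6.42 for PRR9.

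Replication-dependent histone genes, whose messages normally end in a stem-loop without a poly(A) tail, rose in the RAD21L line: 8 of 10 measured members were higher and 2 did not pass, with 9 higher adjusted over the list alone, and the median log2 fold was 2.19 (adjusted p = 3.44e-08 by camera, adjusted p = 0.466 with an estimated correlation). HIST1H2BK (chromosome 6, 27146418 to 27146798) went from 11.9 ± 1.89 to 102 ± 15.7 CPM (log2 3.09 ± 0.22, adjusted p = 3.78e-06), and HIST1H3H (2.48 ± 0.43) and the linker histone HIST1H1C (1.76 ± 0.29) rose too. HIST1H2BC also rose, from 1 count over the 3 double line libraries, so its log2 fold was poorly fixed and ran from 5.39 to 8.19 over the libraries left out. The per-library medians against the double line mean were 2.22 in p1, 1.93 in c1 and 2.17 in c2, and between 0.51 and 0.90 in the parental libraries. Of the genes for cytosolic ribosomal proteins 21 of 42 fell and 21 did not pass, and 28 were lower adjusted over the list alone. Their median was -0.35 (adjusted p = 1.83e-11 by camera, adjusted p = 0.466 with an estimated correlation). Examples were RPS6 (log2 -0.71 ± 0.10, adjusted p = 0.000907), RPL4 (-0.46 ± 0.08), RPS18 (-0.54 ± 0.09) and RPL5 (-0.52 ± 0.09), and the per-library medians were -0.29, -0.44 and -0.28 in p1, c1 and c2.

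**Figure D3:**
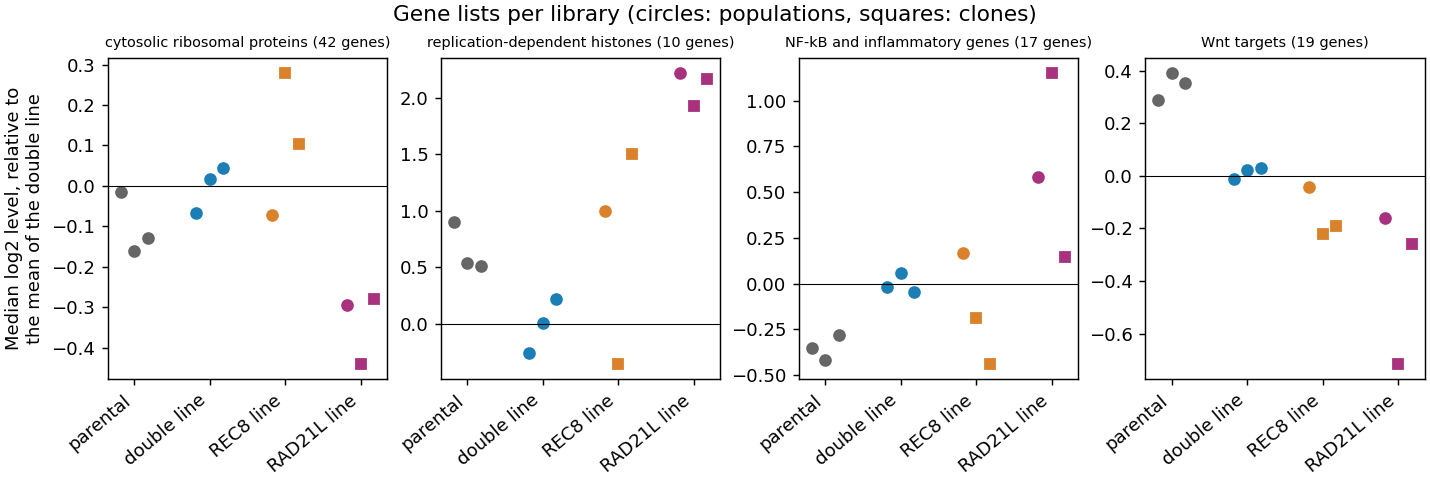
Median log2 level of the measured genes of 4 lists in each library, relative to the mean of the double line, with circles for populations and squares for clones. The ribosomal protein medians of the RAD21L libraries lie between -0.44 and -0.28 and their histone medians between 1.93 and 2.22.

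Of 17 NF-kB and inflammatory genes 6 rose and 11 did not pass, and 8 were higher adjusted over the list alone. Their median was 0.70 (adjusted p = 0.00135 by camera, adjusted p = 0.466 with an estimated correlation). The NF-kB subunit NFKB2 (log2 1.19 ± 0.20, adjusted p = 0.00211) and the cytokine IL18 (1.00 ± 0.18) were among them, and the per-library medians were 0.58 in p1, 1.15 in c1 and 0.15 in c2. Of 29 genes of the unfolded protein and integrated stress response 3 rose, 11 fell and 15 did not pass, with 8 higher and 11 lower adjusted over the list alone and a median of -0.16 (adjusted p = 0.0364 by camera, adjusted p = 0.602 with an estimated correlation). The ATF4 targets PSAT1 (log2 -1.15 ± 0.12, adjusted p = 0.000117), a serine synthesis enzyme, ASNS (-1.33 ± 0.18), asparagine synthetase, and TRIB3 (-0.97 ± 0.13) fell with DDIT4. In its per-library medians clone c1 and double line p2 were both at -0.07. This list was not called without RAD21L line p1 (adjusted p = 0.0979) or with the GC and length trend removed (0.0504). Among hypoxia and glycolysis genes 6 of 27 rose, 2 fell and 19 did not pass, with 7 higher and 3 lower adjusted over the list alone. SLC2A1 (1.34 ± 0.14), NDRG1 (1.53 ± 0.20) and the peptide hormone ADM (1.72 ± 0.25) rose. Camera did not call the list (adjusted p = 0.0702). Of the immediate early and AP-1 list 3 of 24 rose, 7 fell and 14 did not pass, with 4 higher and 9 lower adjusted over the list alone. EGR1, a serum-induced transcription factor, was at -2.00 ± 0.37. Camera did not call the list (adjusted p = 0.0716).

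Of 19 Wnt targets 5 fell, 1 rose and 13 did not pass, and 7 were lower and 1 higher adjusted over the list alone. Their median was -0.36 (adjusted p = 0.00958 by camera, adjusted p = 0.466 with an estimated correlation). ASCL2 (log2 -1.84 ± 0.31, adjusted p = 0.00246), a transcription factor of intestinal stem cells, and SOX9 (-1.17 ± 0.21) fell, whereas LGR5 (1.02 ± 0.22), a receptor on the same stem cells, rose. The Wnt list was not called with the origin of the libraries as a covariate (adjusted p = 0.138) or without the clones (0.0685). LGR5, IL18, CCN2 and TSPOAP1 lost their calls with that covariate, as did SYNGR4 and FANCD2, which also lost them without the clones. HOX cluster genes had a median of -0.31 (adjusted p = 0.00420 by camera, adjusted p = 0.466 with an estimated correlation). Of 23 genes 5 fell and 18 did not pass, with 6 lower adjusted over the list alone, and HOXB9 was at -0.92 ± 0.14. Among epithelial genes 3 of 29 rose, 3 fell and 23 did not pass, with 3 higher and 4 lower adjusted over the list alone. The keratins KRT19 (1.01 ± 0.15) and KRT18 (0.70 ± 0.13) rose, the median was 0.07 and the mean -0.07. Camera did not call the list (adjusted p = 0.688). Of 12 mesenchymal genes 3 rose, with 3 higher adjusted over the list alone, and 9 did not pass. The YAP1 target CCN2 was at 1.81 ± 0.31. Camera did not call the list (adjusted p = 0.137). Of 13 intestinal differentiation genes 2 fell and 11 did not pass, with 3 lower adjusted over the list alone. Camera did not call the list (adjusted p = 0.0783). Of 14 imprinted genes 3 rose, 2 fell and 9 did not pass, with 3 higher and 3 lower adjusted over the list alone. Examples were PLAGL1 at 0.71 ± 0.12, PHLDA2 at 0.82 ± 0.16 and GRB10 at -0.61 ± 0.12. As a list these were not called (adjusted p = 0.975 by camera).

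Of 28 genes of homologous recombination and DNA damage signalling 5 fell and 23 did not pass, and 6 were lower and 1 higher adjusted over the list alone. Their median was -0.19 (adjusted p = 0.00408 by camera, adjusted p = 0.469 with an estimated correlation). The checkpoint kinase CHEK2 fell (log2 -1.12 ± 0.20, adjusted p = 0.00302), as did FANCD2 (-0.48 ± 0.10). That list was not called without clone c1 (adjusted p = 0.0862), without the clones (0.382) or with origin as a covariate (0.117). Of 31 DNA replication genes 2 fell, 1 rose and 28 did not pass, with 1 higher and 2 lower adjusted over the list alone, a median of -0.15 and an adjusted p of 0.126 by camera. Of 30 genes of mitosis and the spindle checkpoint 3 fell and 27 did not pass, with 3 lower adjusted over the list alone (adjusted p = 0.0689 by camera). Of 22 p53 target genes 2 rose, 3 fell and 17 did not pass, with 4 higher and 7 lower adjusted over the list alone (adjusted p = 0.683 by camera). BBC3, which encodes the cell death protein PUMA (log2 -1.61 ± 0.29, adjusted p = 0.00324), and CCNG1 (-0.62 ± 0.10) fell. Of 22 apoptosis regulators 2 rose, 2 fell and 18 did not pass, with 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.295 by camera). The falls were BBC3 and BMF (-1.85 ± 0.35), another BH3-only gene. Of 29 interferon-stimulated genes 2 rose, 2 fell and 25 did not pass, with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.890 by camera). Of 26 cholesterol biosynthesis genes 1 rose, 1 fell and 24 did not pass, and 0 were called by edgeR adjusted over the list alone. Their median was -0.30 (adjusted p = 0.00839 by camera, adjusted p = 0.602 with an estimated correlation). Without RAD21L line p1 the adjusted p was 0.483.

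The number of calls between the RAD21L line and the double line varied with the libraries left out: without double line p1, p2 or p3 the counts were 785, 829 and 780, and without clone c2 803. With origin as a covariate 540 genes were called, 1037 without the clones, and 383 with a log2 fold of at least 1 in size. Of the 86 named genes called, 54 kept their call with each library left out, among them each gene named so far for this comparison but STAG3. DESeq2 called 1682 genes, and the authors' deposited table holds 603 higher and 599 lower, of which 1009 were called here in the same direction.

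**Figure D4:**
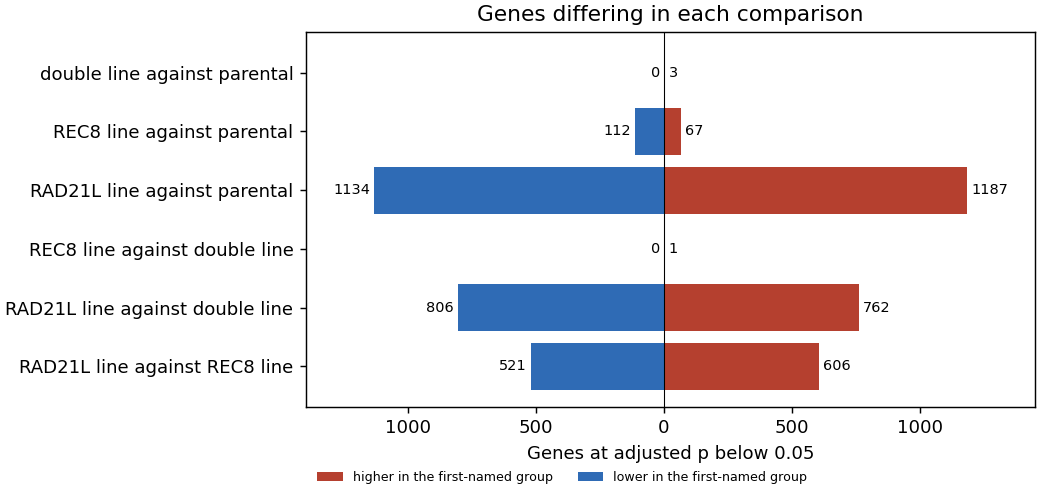
Number of genes at an adjusted p below 0.05 in each of the 6 comparisons, higher to the right and lower to the left of 0. The RAD21L line differs from the other groups in 1127 to 2321 genes, the REC8 line from the double line in 1.

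Against the parental cells the RAD21L line differed in 2321 genes, 1187 higher and 1134 lower. Among genes so named, without the transgenes, the largest rises were again CPA4 (log2 7.25 ± 0.90, adjusted p = 0.000169) and PRR9 (log2 6.56 ± 0.65, adjusted p = 3.68e-05), followed by KRTAP2-3 (5.31 ± 0.65), ANKRD1 (adjusted p = 0.000415) and PIK3AP1 (4.44 ± 0.66), an adaptor of PI3-kinase. ATOH8, a transcription factor, fell from 31.4 ± 3.48 to 0.970 ± 1.21 CPM (log2 -5.04 ± 0.65, adjusted p = 0.000227), and SH3PXD2A (-4.57 ± 0.50) and KCNJ8 (-4.30 ± 0.54) fell too. CST1 had 0, 5 and 0 counts in RAD21L line p1, c1 and c2, and its log2 fold lay between -9.19 and -4.12 over the libraries left out. PCP4, a calmodulin-binding protein gene, was at 0 CPM in p1 and c1 and 0.292 in c2, with a log2 fold between -7.54 and -4.81 (adjusted p = 0.0191), a call that ended without RAD21L line p1, c1 or c2 or without parental p1 (adjusted p up to 0.0599).

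Of 17 NF-kB and inflammatory genes 9 rose and 8 did not pass, and 10 were higher adjusted over the list alone. Their median was 1.26 (adjusted p = 1.79e-05 by camera, adjusted p = 0.360 with an estimated correlation). IL18 was at 1.99 ± 0.18, NFKB2 at 1.61 ± 0.20 and CXCL8, a neutrophil chemokine, at 3.78 ± 0.58. Of 19 Wnt targets 11 fell, 1 rose and 7 did not pass, and 15 were lower and 2 higher adjusted over the list alone. Their median was -0.80 (adjusted p = 3.59e-05 by camera, adjusted p = 0.360 with an estimated correlation). Members included ASCL2 at -2.58 ± 0.31, LEF1 at -1.36 ± 0.20 and LGR5 at 1.43 ± 0.22. Of 13 intestinal differentiation genes 5 fell, 1 rose and 7 did not pass, with 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.0255 by camera, adjusted p = 0.530 with an estimated correlation). Among them were the brush border gene VIL1 at -2.67 ± 0.43 and the intestinal transcription factor CDX2 at -0.78 ± 0.16. The list was not called without clone c2 (adjusted p = 0.0860) or with origin as a covariate (0.355). Of 27 hypoxia and glycolysis genes 9 rose, 1 fell and 17 did not pass, with 9 higher and 2 lower adjusted over the list alone (adjusted p = 0.00752 by camera, adjusted p = 0.360 with an estimated correlation). SLC2A1 stood at 2.00 ± 0.14. Of 10 histone genes 7 rose and 3 did not pass, and 8 were higher adjusted over the list alone. Their median was 1.27 (adjusted p = 0.000302 by camera, adjusted p = 0.530 with an estimated correlation). Of 42 ribosomal protein genes 13 fell and 29 did not pass, and 13 were lower adjusted over the list alone. Their median was -0.22 (adjusted p = 1.79e-05 by camera, adjusted p = 0.725 with an estimated correlation). HOX cluster genes had 7 of 23 members lower and 1 higher, or 8 and 1 adjusted over the list alone (adjusted p = 0.0160 by camera, adjusted p = 0.530 with an estimated correlation). This list was not called without clone c2 (0.0861). Genes of homologous recombination and DNA damage signalling had 6 of 28 lower and 1 higher, or 10 and 1 adjusted over the list alone (adjusted p = 0.00205 by camera, adjusted p = 0.530 with an estimated correlation). Their adjusted p was 0.279 without the clones and 0.0817 with origin as a covariate. Of the cholesterol genes 1 of 26 was higher, also adjusted over the list alone (adjusted p = 0.0236 by camera, adjusted p = 0.737 with an estimated correlation), and the adjusted p was 0.603 without RAD21L line p1. Leaving out parental p1, p2 or p3 gave 1264, 1407 or 1258 called genes and leaving out clone c2 1458, and 997 were called with origin as a covariate. DESeq2 called 1258 higher and 1107 lower, and the authors' deposited table holds 897 higher and 821 lower, of which 1505 were called here in the same direction.

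The RAD21L and REC8 lines, compared directly, differed in 1127 genes, 606 higher and 521 lower in the RAD21L line. PRR9 (log2 4.70 ± 0.62, adjusted p = 0.000822), CPA4 (4.43 ± 0.78, adjusted p = 0.00385) and CCN2 (3.22 ± 0.36, adjusted p = 0.000284) had the largest rises among genes so named, without the transgenes. The fold of CPA4 ran from 3.12 to 6.28 over the libraries left out, with 7.77 CPM in REC8 line A against 1.08 in p1 and 0.447 in B, and 142 in c1 against 27.5 in p1 and 24.8 in c2. KRTAP2-3 (2.86 ± 0.57) and ATP8A2 (2.77 ± 0.57) were also higher. CCN2 stood at 137 ± 59.0 CPM against 14.3 ± 6.89 in the REC8 line. KCNJ8 (log2 -3.30 ± 0.63, adjusted p = 0.00616), DDIT4 (-2.46 ± 0.35, adjusted p = 0.00137) and the sulfotransferases SULT1C3 (-3.27 ± 0.71) and SULT1C2 (-2.32 ± 0.45) were lower. KIT, a receptor of growth signals, was called lower (log2 -3.72 ± 0.84, adjusted p = 0.0151). Clone B held 224 CPM against 24.9 in p1 and 18.3 in A. The call ended without RAD21L line c1 or c2 (adjusted p up to 0.0539), by voom weights (0.119), with these 6 libraries alone (0.112) and without the clones (0.174). SMC1B was also called higher in the RAD21L line (log2 1.02 ± 0.27, adjusted p = 0.0320), a call that ended without c1, c2, REC8 line B or REC8 line p1 (adjusted p up to 0.0951) and by DESeq2 (0.0593).

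By list, 31 of 42 ribosomal protein genes were lower in the RAD21L line than in the REC8 line and 11 did not pass, and 40 were lower adjusted over the list alone. Their median was -0.43 (adjusted p = 1.37e-19 by camera, adjusted p = 0.559 with an estimated correlation). RPS6 was at -0.68 ± 0.10 and RPLP0 at -0.67 ± 0.12. Of 10 histone genes 5 rose and 5 did not pass, with 5 higher adjusted over the list alone and a median of 1.07 (adjusted p = 5.73e-05 by camera, adjusted p = 0.564 with an estimated correlation) and HIST1H2BK at 2.17 ± 0.21. Of 17 NF-kB and inflammatory genes 7 rose, 1 fell and 9 did not pass, and 9 were higher and 1 lower adjusted over the list alone. Their median was 0.76 (adjusted p = 2.39e-05 by camera, adjusted p = 0.343 with an estimated correlation). Examples were IL18 at 1.09 ± 0.18 and BIRC3, an inhibitor of apoptosis, at 1.87 ± 0.34. Clone c2 (0.15) lay below REC8 line p1 (0.17) in this list's median against the double line mean. Epithelial genes had 5 of 29 members higher and 1 lower, 10 higher and 1 lower adjusted over the list alone, and a median of 0.20 (adjusted p = 0.00744 by camera, adjusted p = 0.879 with an estimated correlation). KRT19 was at 1.18 ± 0.15 and KRT18 at 1.06 ± 0.13. This list was not called without clone c1 (adjusted p = 0.150) or REC8 line A (0.120), or without the clones (0.390). Mesenchymal genes had 2 of 12 higher, 2 higher and 1 lower adjusted over the list alone, and a median of 0.36 (adjusted p = 0.0419 by camera, adjusted p = 0.343 with an estimated correlation). They were not called without c1 (0.0560), c2 (0.111) or A (0.120), under the strict low-count filter (0.0623) or without the clones (0.237). DNA replication genes had 2 of 31 lower, 5 lower adjusted over the list alone, and a median of -0.16 (adjusted p = 0.0389 by camera, adjusted p = 0.879 with an estimated correlation). They were not called without c1 (0.242), A (0.313) or REC8 line p1 (0.265), without the clones (0.135) or with the GC and length trend removed (0.0576). PSAT1 (-1.09 ± 0.12) and TRIB3 (-0.89 ± 0.13) were lower and SLC2A1 (0.94 ± 0.14) and LGR5 (1.56 ± 0.24) higher. Without REC8 line B 717 genes were called and without clone c1 742. Without the clones, with 1 library per line, 140 were. CCN2, PSAT1, TRIB3, SLC2A1, LGR5, KRT18, KRT19 and HIST1H2BK were still called when the fit held these 6 libraries, where 73 genes passed. Of the 72 named genes called, 10 kept their call under every alternative but the fold limit. DESeq2 called 727 higher and 574 lower, and the authors' deposited table holds 560 higher and 465 lower.

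The REC8 and RAD21L lines shared part of their distance from the parental cells. Both were called in the same direction in 53 higher and 85 lower genes, where independent lists of the same sizes would share 6.01 and 10.1, an expectation that leaves out the shared control libraries. Their log2 folds against parental cells had a Pearson correlation across genes of 0.585, against 0.436 in 20 simulated sets of unchanged groups that shared the control libraries, and a covariance of 0.163 against 0.0355. Against the double line the correlation was 0.505, within the simulated range (mean 0.486, highest 0.517), and the covariance 0.121 against 0.0434. By edgeR 627 genes had an unadjusted p under 0.05 in both and the same sign, against 125 on average and at most 143 in these sets without changes. In the data 1584 genes of the REC8 line and 3527 of the RAD21L line had such a p against the double line. Unrelated changes of that number would overlap too, and no simulated set held them. The simulated sets gave each library of a gene the same dispersion, although the groups differed in spread. The correlation and the count of 627 genes can thus neither show nor exclude a shared response against the double line. Genes are not independent replicates, and 3 controls were too few to split between the lines. SH3PXD2A, IGF2 and CST1 were among the named genes lower in both lines against parental cells.

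Folds of the mitotic cohesin genes were small beside those of the transgenes. In the RAD21L line against the double line RAD21 was at -0.24 ± 0.12, SMC1A at -0.18 ± 0.10, SMC3 at -0.21 ± 0.10 and STAG2 at -0.15 ± 0.11, and these 4 did not pass in any of the 6 comparisons. STAG1 was higher in the RAD21L line than in parental cells (log2 0.33 ± 0.10, adjusted p = 0.0394), and its call ended without any 1 of the parental libraries, RAD21L line p1 or clone c1. Of the 19 genes of mitotic cohesin and its regulators PDS5A, a cohesin release factor, was lower against the double line (log2 -0.33 ± 0.10, adjusted p = 0.0421), a call that ended without any 1 of the double line libraries, c1 or c2. The list had a median of -0.20 (adjusted p = 0.0364 by camera, adjusted p = 0.466 with an estimated correlation). It was not called without clone c1 (adjusted p = 0.0937), double line p2 (0.0899), the GC and length trend (0.0504) or the clones (0.278), or with origin as a covariate (0.117). Of the 14 genes of condensin and the SMC5/6 complex NSMCE4A was lower in the RAD21L line than in the double line (log2 -0.61 ± 0.11, adjusted p = 0.00408) and 13 did not pass, and camera gave an adjusted p of 0.129. That call ended without the clones (0.0861). Of the 40 genes of meiosis and the germline beside the transgenes 7 were expressed enough to test, and by edgeR 0 of them were called in any comparison. Camera gave the list an adjusted p of 0.867 in the RAD21L line against the double line. Lists with fewer than 5 measured genes were not tested. Of the markers of other cell types KRT10 of keratinocytes was higher in the RAD21L line than in the double line (log2 0.77 ± 0.15, adjusted p = 0.00517), COL1A1 of fibroblasts was at log2 1.25 (adjusted p = 0.0805), and CLDN5 of endothelial cells was not called. Against parental cells KRT10 (log2 0.88 ± 0.14, adjusted p = 0.000996) and COL1A1 (log2 1.42 ± 0.42, adjusted p = 0.0283) were both higher. No leukocyte marker, X-linked cancer-testis antigen or clustered protocadherin beta gene was measured well enough to test. The 13 mitochondrially encoded genes of the list were not found by symbol among the authors' deposited counts, so their levels could not be judged.

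Of 132 tests of a list in a comparison 43 were called by camera with its preset correlation between genes, and 0 of them held with an estimated correlation, where the lowest adjusted p was 0.343. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 8 lists in the RAD21L line against parental cells, 8 against the double line, 4 against the REC8 line and 0 in the other 3 comparisons. Its mixed form, which asks whether genes of a list change in either direction, called 2, 12, 21, 4, 21 and 19 lists in the double, REC8 and RAD21L lines against parental cells, the REC8 and RAD21L lines against the double line and the RAD21L against the REC8 line. Median, mean and test had the same sign in the 43 called lists. Among lists not called they differed in sign for NF-kB genes in the REC8 line against the double line (median -0.12, mean 0.23), for stress response genes in the RAD21L line against parental cells (median 0.08, mean -0.11), and in 18 other cases.

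Across the 4 groups together 1899 of 12604 genes differed (15.1%). Libraries of a group lay 0.338 log2 units apart on average in parental cells, 0.434 in the double line, 0.642 in the REC8 line and 0.589 in the RAD21L line. Parental and double line libraries lay 0.431 apart on average, against 0.401 to 0.450 within the double line. Their pairs with parental p1, the library with the most counts, lay 0.374 to 0.396 apart. Pairs with parental p2 or p3 lay 0.438 to 0.477 apart, so some exceeded the double line's own spread. Chromosome 19 genes (860) had a median log2 fold of 0.13 in the REC8 line against parental cells (adjusted p = 0.00340 by camera, adjusted p = 0.373 with an estimated correlation). The median was 0.11 against the double line (adjusted p = 0.00588 by camera, adjusted p = 0.467 with an estimated correlation). With the GC and length trend removed these were 0.05 and 0.04, with adjusted p-values of 0.865 and 0.983. In RAD21L line c1 the 841 tested genes of chromosome 2 had a median of -0.33 against the parental mean.

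**Figure D5:**
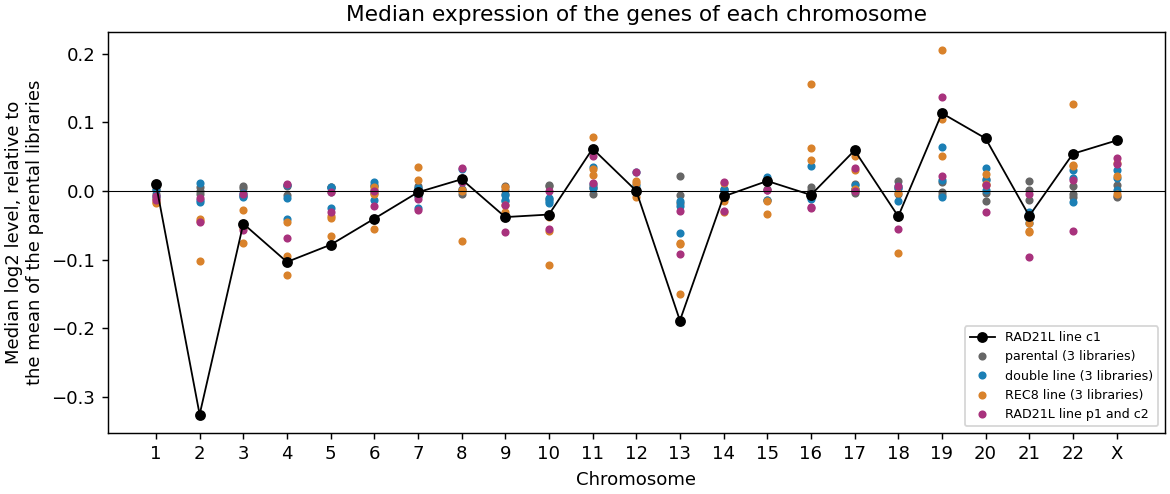
Median log2 level of the tested genes of each chromosome per library, relative to the mean of the parental libraries, with RAD21L line c1 as black points joined by a line. Chromosome 2 of that library lies at -0.33.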

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

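The tests of single-cell cloning and of cells in S phase were chosen only after the results were seen. What follows are differences between the RAD21L and REC8 lines, whose changes against the double line were tested against each other in 1 contrast. By the fit to all 12 libraries the changes differed in 1127 genes. A fit of these 6 libraries called 73, and voom weights gave 407. The median differences of the called lists were -0.16 for DNA replication, 0.76 for NF-kB and inflammatory genes, 0.20 for epithelial genes, 0.36 for mesenchymal genes, 1.07 for replication-dependent histones and -0.43 for cytosolic ribosomal proteins. With an estimated correlation none of these 6 lists was called (adjusted p from 0.343 to 0.879), and DNA replication (0.135), epithelial (0.390) and mesenchymal genes (0.237) were not called without the clones.

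Of 42 ribosomal protein genes 21 were lower in the RAD21L line than in the double line (median -0.35) and 31 lower than in the REC8 line (median -0.43). The list was not called with an estimated correlation (adjusted p = 0.466 and 0.559). A bias from GC content and gene length is argued against, because the median against the double line was -0.32 with that trend removed and 23 members were still called lower. With population or clone as a covariate the median was -0.39 and 12 members were called lower. This argues against a shift shared by all clones as the whole cause and cannot exclude shifts of single clones. That covariate took the REC8 libraries A and B as clones. Without it, RAD21L line p1, a population, was at -0.29 against -0.07 to 0.05 in the double line libraries. The line itself, its selection and the RAD21L transgene stay open and untested.

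Of 10 replication-dependent histone genes 8 were higher in the RAD21L line than in the double line (median 2.19) in poly(A)-selected libraries, and the list was not called with an estimated correlation (adjusted p = 0.466). More cells in S phase would raise the DNA replication list, but its median was -0.15 (95% interval over its genes -0.25 to -0.05). Genes of a list are not independent, and this interval leaves out the spread between libraries. Its per-library medians were -0.02, -0.22 and -0.16 in RAD21L line p1, c1 and c2. They overlapped those of double line p1, p2 and p3, at -0.22, 0.14 and 0.07. A rise of that list was thus not seen, but a change in the share of S phase cells is not excluded. With population or clone as a covariate the histone median was 2.12 and 6 histone genes were called higher. This argues against a shift shared by all clones as the whole cause. It cannot exclude shifts of single clones, as REC8 line A and B lay at -0.36 and 1.51. RAD21L line p1, a population, was at 2.22. The double line libraries lay at -0.26 to 0.22, the parental libraries at 0.51 to 0.90 and REC8 line p1 at 0.99. A larger share of RNA without a poly(A) tail in these libraries cannot be told apart from a change in the histone messages, because 1 other gene of that kind, BCYRN1, was measured (log2 -0.31, chosen after its value was seen). A biological difference of the line stays open and untested.

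The 10 splits of 6 libraries into 3 and 3 were too few for a share under 0.05 in any of the 6 comparisons, and in each of them 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 3 and 1 for the double line against parental cells, 179 and 0 for the REC8 line against parental cells, and 2321 and 0 for the RAD21L line against parental cells. They were 1 and 0 for the REC8 line against the double line, 1568 and 0 for the RAD21L line against the double line, and 1127 and 93 for the RAD21L line against the REC8 line. For the test over the 4 groups 1 of 100 splits, the real one with 1899 genes, gave as many, and the highest other gave 670. A difference of this size from a random split of the libraries is thus unlikely. Libraries of a line share its transgenes and selection, so this shows that the lines differ and not why.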

How the results depend on the processing

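The tests with parental p1 thinned, voom weights, the GC and length trend removed, both REC8 clones left out, chromosome 2 left out, and an estimated correlation for chromosomes were chosen only after the results were seen. For the double line against parental cells (3 genes) 12 were called with no filter, 17 by DESeq2, and 250 without the clones. The count was 253 with only the 6 libraries, 130 with voom weights, and 2 with any 1 library left out. With the replicate number as a block 150 were called; same-numbered libraries had correlations across genes of -0.06, 0.002 and -0.08, so the numbers do not pair them. For the REC8 line against parental cells (179) 467 were called with no filter, 436 by DESeq2, 8 with origin as a covariate, 87 with a log2 fold of at least 1, 12 without both REC8 clones, and 10 to 695 with 1 library left out. For the RAD21L line against parental cells (2321) the counts were 997 with origin, 1491 without the clones, 663 with the fold limit and 1258 to 2391 with 1 library left out. For the REC8 line against the double line (1) they were 53 with no filter, 75 by DESeq2, 11 without the clones, 1 to 191 with 1 library left out, and 2 with origin, with only the 6 libraries and without both REC8 clones. For the RAD21L line against the double line (1568) they were 540 with origin, 1037 without the clones, 383 with the fold limit and 780 to 1591 with 1 library left out. For the RAD21L line against the REC8 line (1127) they were 140 without the clones and 140 without both REC8 clones, 73 with only the 6 libraries, 268 with the fold limit, 407 with voom weights and 717 to 1334 with 1 library left out. The test over the 4 groups (1899) gave 845 with origin and 1139 without the clones. Of the list tests (43 called) 0 were called with an estimated correlation, 20 by fry, 79 by its mixed form and 37 to 48 with 1 library left out. The correlation across genes of the REC8 and RAD21L folds against the double line (0.51) was 0.65 over genes called in either comparison, which were chosen by these folds and had no simulated counterpart. Of the 2 chromosome calls 0 were left with the GC and length trend removed and 0 with an estimated correlation. Of 274 calls of named genes, 8 were lost with the GC and length trend removed, 11 by DESeq2, 2 with RLE factors, 9 with no filter, 7 with p1 thinned, and 37 with voom weights. Another 81 were lost with only the 6 libraries, 84 with origin, 102 without the clones, and 93 in at least 1 library left out. Of 98 calls in comparisons with the REC8 line, 73 were lost without both REC8 clones. Of 269 tested under the strict filter 1 was lost, and of 230 tested without chromosome 2, 0 were lost by edgeR. A fold limit removes calls by construction. Beside the spread of the groups, taken up next, no other cause of these differences was tested. The fit to all 12 libraries shared the spread of a gene over the 4 groups, although the groups differed in spread. Voom quality weights were 0.480 to 1.01 in the REC8 and RAD21L libraries and 0.767 to 2.40 in the others. The double line against parental cells thus took in spread from wider groups, and the RAD21L against the REC8 line from narrower ones. Fits of only the 6 libraries, with the spread of the 2 groups compared, moved both counts that way. The first went from 3 to 253 and the second from 1127 to 73, and voom weights gave 130 and 407. Those fits of 6 libraries also had fewer residual degrees of freedom, so the part due to spread was not separated. Fewer libraries gave fewer calls in some comparisons and more in others. The pseudocount alternative, which is for normalized values, was not run. The block was run only for the double line against parental cells, so not in comparisons with the RAD21L line or with the REC8 line, whose numbers are unclear. Depth of 2202836 to 3531985 counts in 11 libraries may limit the calls in genes of low level, which was not tested.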

Other observations

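The tests of GC content and of a part of the chromosome for chromosome 2 were chosen only after the result was seen. Single libraries stood apart in a few genes. PTGS2 was at 1477 CPM in REC8 line B, against 7.59 and 2.74 in REC8 line p1 and A. PLA2G4A, a phospholipase that releases the substrate of that enzyme and was chosen after its values were seen, was at 274 CPM against 4.34 and 8.68. These were the 2 genes at least 8-fold above every other library in clone B among genes of at least 10 CPM. By the same measure VPS9D1 stood out in RAD21L line c1 and ADGRL2 in RAD21L line c2, both chosen after their values were seen, and 0 genes did so in any population. At least 8-fold below every other library were 4 genes in REC8 line B (FSCN1, IQGAP2, TCEAL9 and 1 without a symbol), 3 in RAD21L line c1 (TFCP2, S100A4 and BLOC1S5-TXNDC5), and CEMIP in REC8 line A. The same held for PYURF in RAD21L line c2, SIK1B in parental p2 and HIST2H2AA3 in double line p2, and each of these genes was chosen after its values were seen.

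Levels of a few named genes, chosen after their values were seen, went the same way in several lines. SH3PXD2A had group means of 52.5 CPM in parental cells, 27.9 in the double line, 6.49 in the REC8 line and 2.23 in the RAD21L line. IGF2 had 47.1, 28.5, 21.0 and 15.6 CPM and CST1 17.2, 3.24, 1.14 and 0.619 CPM in the same order, whereas EEF1A2 had 98.4, 166, 744 and 433 CPM. For these genes no order of the groups was tested.

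Genes on chromosome 2 were lower in RAD21L line c1, with a median of -0.33 against the parental mean over 841 genes, of which 75.9% were lower against 49.3% of 11763 genes elsewhere. A bias from GC content and gene length is argued against, because the median was -0.29 with that trend removed, outside the range of -0.11 to 0.09 of the other chromosomes of this library. A change in a small part of the chromosome is argued against, because 13 of 13 windows of 20 Mb (100%) had a median below 0 and 12 lay below every other library. In the window from 40 to 60 Mb the median was -0.15 and another library reached -0.19, so a drop there was not shown. The windows starting at 100000001, 140000001, 160000001 and 180000001 had medians of -0.32, -0.42, -0.50 and -0.34. The lowest other library reached -0.29, -0.29, -0.33 and -0.25 there, so a lower level in these windows was not particular to this clone. Fewer copies of most or all of chromosome 2 in this clone are a candidate explanation. The more and the less expressed genes were lower alike, with a difference of their medians of -0.0070 (95% interval -0.0936 to 0.0876). Any even shift of the chromosome would give this too, and the size of the drop was not set against a number of copies. DNA copy number was not analysed here, and fewer copies remain a hypothesis.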
